A study of Mus musculus with 2 samples.

How the data were processed

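The series holds 2 single-cell RNA libraries from mice, 1 of the WT group and 1 of the Il7rKO group. In each, lymph nodes from several sites were pooled and digested with enzymes, and live cells positive for the red reporter tdTmt and for MHC class II were sorted before droplet capture with the 10x Chromium V3 3′ chemistry. The cell type or gene that drives tdTmt and the part of Il7r changed in the knockout are not described in the labels. Each library holds 1 pool, and the labels do not say how many mice it came from.

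The deposited values are UMI counts per gene and barcode, whole numbers with no scaling, in filtered matrices of 33698 features each. Cell Ranger 8.0.1, Scanpy 1.10.2 and the mouse genome build mm10 were used by the authors, per the submitters' processing notes, which do not say at which step. The feature list contains the reporters gfp and tdTomato beside mouse genes, and its annotation release is not given in the sources used here. Of the features, 31961 have an ID in GENCODE vM21, from which gene positions were taken (GRCm38, the same build as mm10). A symbol shared by several IDs occurred 26 times, and 4 genes of the fixed lists were not among the features.

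Barcodes with fewer than 500 genes or more than 10% mitochondrial UMIs were left out. In WT, 158 of 7740 barcodes had too few genes and 110 too many mitochondrial UMIs, and 7535 (97.4%) passed. In Il7rKO, the numbers were 63 and 51 of 784 barcodes, and 704 (89.8%) passed. Scrublet, run per library, then called 6 WT cells (0.0796%) and 4 Il7rKO cells (0.568%) doublets, and these were removed. At that rate the caller is taken not to have worked for WT, since the labels do not say that doublets were removed before deposit. Doublets can therefore remain among the kept cells, and the closing section weighs them where T cell genes appear in dendritic cells. The 7529 WT and 700 Il7rKO cells kept had medians of 14892 and 28974.5 UMIs and of 3907 and 5036.5 genes. Only 2 barcode sequences occurred in both libraries.

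Cells of both libraries were clustered together (Scanpy 1.11.5, AnnData 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 under Python 3.11.15, with plots from matplotlib 3.10.9). Counts were scaled to 10000 per cell and logged. The 2000 most variable genes gave 30 principal components, and a graph of 15 neighbours was split with the Leiden method at resolution 1. Il7r, the reporters, Xist and Y-linked genes, immunoglobulin and T cell receptor variable segments, and mitochondrial and ribosomal genes did not enter the clustering. No batch correction was applied, because library and group are the same. This gave 27 clusters.

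Clusters were named from 20 marker lists, which, like the filters, the 23 gene lists, the statistics, the rule for named genes and most alternative settings, were fixed before the data were examined. A cluster took the name of the list with the most members among its 50 leading genes, or, with fewer than 2 there, of the list with the highest mean log2 ratio over the median cluster. A name needed at least 3 markers detected in 10% of cells and at a level of 2 times that median. This naming rule was written after the data had been seen. It left 8 clusters unnamed, whose shares are reported by reason, and 13 marker lists named no cluster. Of the classes named, the 4 with at least 30 cells in each library were compared: Aire APC-like, NK-like, ILC3/LTi-like and migratory DC-like. One of their clusters (26), in the Aire APC-like class, carried 11 of the 12 migratory dendritic cell markers as well as 9 of its own 15.

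A class share is the percent of kept cells, with an exact binomial (Clopper-Pearson) 95% interval. A gene's level is its CPM, the UMIs of the gene over all UMIs summed over the class in a library, with an exact Poisson 95% interval, and ratios have exact conditional binomial intervals. All of these cover counting error only. With 1 library per group there is no test between groups, no p-value and no count of changed genes. A log2 ratio is that of CPM plus 5, Il7rKO over WT, except for Il7r, whose ratios have nothing added. Where 1 library had a count of 0, the fold was taken against 3 UMIs in the class.

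For a gene list, the members with at least 10 UMIs expected in each library gave a median log2 ratio. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these 2 libraries. Lists below the percentile of 2.5 or above 97.5 are called outside the random range, and lists with fewer than 3 measured members have no median.

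The rule for named genes took Il7r first. In each of the 3 classes with the most cells in the library that has fewer of them, it then took the 10 highest and the 10 lowest log2 ratios, and in the migratory DC-like class the 3 highest and 3 lowest. A gene needed at least 50 CPM and 30 UMIs where it was higher, and at least 10 UMIs expected in the other library at that level. Variable segments, mitochondrial and ribosomal genes, genes named Gm or Rik, Xist and Y-linked genes were left out of this ranking. The rule also allowed up to 4 members of each list. After the data had been seen, that part was narrowed to 4 members of the IL-7 receptor signalling list and 2 members of each list outside the random range, and the other named genes are class markers, reporters, genes that lead a cluster, or genes chosen after their values were seen, which the text says where they appear. A few genes that the rule takes are not named, were not replaced by others, and did not enter the set of genes shifted in 3 classes.

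The steps that compute ratios, intervals and list percentiles were tested on simulated data, drawn for the 33698 genes of each of the 4 classes with 200 genes changed. Each gene was drawn as an independent Poisson count per class and library, the model that the intervals assume. Spread between cells and genes that vary together were not simulated. The test therefore checks the calculation and not whether the intervals or list percentiles hold for these cells. At true log2 ratios of 1.0, −1.0, 2.0 and −2.0, the intervals held the true ratio for 86%, 98%, 98% and 96% of genes in Aire APC-like cells, for 98%, 98%, 96% and 90% in NK-like, for 96%, 90%, 96% and 98% in ILC3/LTi-like, and for 94%, 98%, 94% and 100% in migratory DC-like cells. The log2 ratio of CPM plus 5 was nearer to 0 than the true value: in the same order of true ratios its medians were 0.75, −0.78, 1.68 and −1.02 in Aire APC-like, 0.89, −0.72, 1.82 and −1.47 in NK-like, 0.91, −0.79, 1.86 and −1.62 in ILC3/LTi-like, and 0.84, −0.81, 1.84 and −1.55 in migratory DC-like cells, so the log2 ratios reported can understate a difference. For unchanged genes the intervals held the true ratio for 94.3%, 96.25%, 95.4% and 95.95%, in that order of classes. In each class, 20 of the 20 most extreme genes had been changed in the direction found, and a raised list of 12 genes had a percentile of 100. Of 100 lists of unchanged genes, 1, 6, 5 and 9 fell outside the random range.

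Each result was recomputed under alternative settings fixed in the same way: no barcode filter, or at least 1000 genes and at most 5% mitochondrial UMIs; doublet calls kept; Leiden resolutions of 0.5 and 2; libraries clustered separately; WT drawn down to as many cells as Il7rKO; median-ratio scaling; CPM without immunoglobulin, mitochondrial and ribosomal genes; 1 or 20 CPM added; the mean over cells; and genes with 1 UMI in either library. Shares of cells with a UMI were recomputed with each cell thinned to 2000 or 1000 UMIs, which left out 290 WT and 17 Il7rKO cells, or 62 and 3. Further alternatives were added after seeing the data: removing the 454 WT and 4 Il7rKO cells with the highest doublet scores (0.8% per 1000 barcodes), thinning to 2000 UMIs before clustering, weighting WT clusters to the Il7rKO mix, and leaving out the cell of each library with most UMIs of a gene. No deposited file was left out.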

Results

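Live tdTmt+ MHCII+ cells sorted from pooled mouse lymph nodes were profiled by droplet-based 3′ RNA sequencing in 2 groups, WT and Il7rKO, with 1 library each. Il7r encodes the alpha chain of the interleukin-7 receptor, on which T cells and innate lymphoid cells depend. The WT library had 7740 barcodes and 131790890 UMIs, with a median of 14675.5 UMIs per barcode. The Il7rKO library had 784 barcodes and 26312639 UMIs, with a median of 27194.5. After filtering, 7529 WT and 700 Il7rKO cells were compared. No difference below has a replicate check, and each interval is a 95% interval for counting error only.

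The first comparison asks how the Il7r transcript itself differed between the libraries. Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176 on GRCm38, minus strand) was lower in Il7rKO and still detected. Over all kept cells its level was 1686 CPM in WT and 473 CPM in Il7rKO, which is 28.1% of WT (27.6 to 28.6). Within classes the Il7rKO level was 56.1% of WT in Aire APC-like cells (53.1 to 59.2; 280 against 157 CPM), 55.8% in ILC3/LTi-like cells (54.0 to 57.6; 2675 against 1493 CPM), 37.2% in NK-like cells (36.1 to 38.4; 2106 against 784 CPM) and 71.0% in migratory DC-like cells (66.2 to 76.1; 515 against 366 CPM). The difference over all cells was thus larger than in any of these 4 classes, whose shares differed between the libraries. The class values depend on the clustering, most in Aire APC-like cells. There the log2 ratio of Il7r was −0.83, but −1.52 with libraries clustered separately. In the migratory DC-like class, Il7r was 457 CPM in WT and 403 in Il7rKO in cluster 14, and 531 and 188 in cluster 15, with 8 Il7rKO cells. Cluster 15 was 74.7% of the WT class, and most of its WT cells held T cell RNA. WT T cell-like cells had Il7r at 2125 CPM. How much of the WT migratory DC-like level is T cell RNA was not tested. The 3′ tag may lie outside the changed part of the gene, in which case the level checks nothing about the allele.

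Il7r was detected in 94.6% of WT cells and 76.6% of Il7rKO cells, at median depths of 14892 and 28974.5 UMIs. In Aire APC-like cells the share was 81.3% in WT and 57.3% in Il7rKO, and with every cell thinned to 2000 UMIs it was 36.4% and 15.1%. In NK-like cells it was 96.1% and 86.7%, or 90.4% and 55.6% after thinning. ILC3/LTi-like cells had 98.3% and 98.5%, or 94.5% and 85.1% after thinning, and migratory DC-like cells had 92.4% and 91.3%, or 48.9% and 51.1%. WT macrophage-like cells, a type that should lack Il7r, had a UMI of it in 61.5% of 65 cells (median depth 29964 UMIs), or 18.8% after thinning, at 157 CPM. The thinned share of Il7rKO Aire APC-like cells (median depth 54435.5 UMIs) was not above that of these WT macrophage-like cells, which come from the library with the higher Il7r level. Against their own library, Il7rKO Aire APC-like cells, at 157 CPM (151 to 164), were above its macrophage-like cells, at 41.0 CPM (18.8 to 77.9), and its cDC1-like cells, at 16.4 CPM (4.46 to 41.9), so their Il7r UMIs are not shown to be background. Those were only 4 and 3 cells, and the 4 had the macrophage gene Lyz2 at 100 CPM against 13238 in WT, so they are a poor reference.

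**Figure D1:**
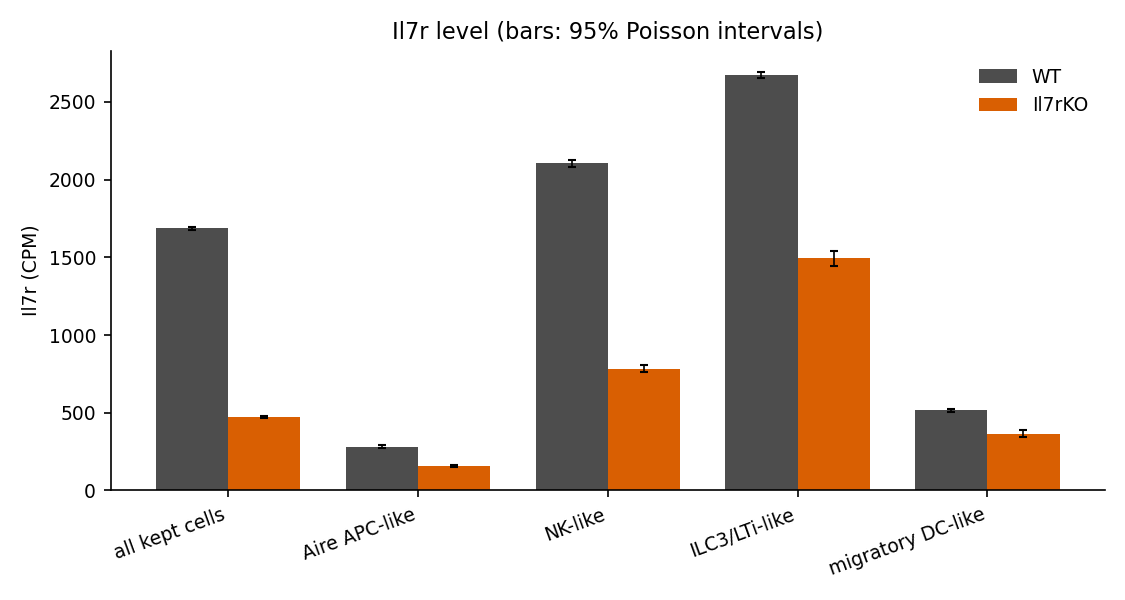
Il7r level in CPM of summed UMIs for all kept cells and for each compared class, WT beside Il7rKO, with exact Poisson 95% intervals (counting error only). Il7rKO was lower in each class, from 37.2% of WT in NK-like cells to 71.0% in migratory DC-like cells. The WT migratory DC-like level includes cells that held T cell RNA, and in cluster 14 of that class the levels were 457 and 403 CPM.

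The second comparison asks which cells passed the sort in each group. Aire APC-like cells, which carry Aire, the regulator that lets tissue antigens be displayed for tolerance, were 5.10% of WT cells (4.61 to 5.62) and 35.1% of Il7rKO cells (31.6 to 38.8), 6.89-fold higher (5.85 to 8.11). NK-like cells were 13.4% (12.6 to 14.2) and 32.3% (28.8 to 35.9), 2.42-fold higher (2.08 to 2.79). No list fixed for this work separates NK cells from other innate lymphocytes that carry NK markers. Cluster 5, with 731 WT and 186 Il7rKO cells, had 6 of 8 NK markers and Il7r at 2050 and 753 CPM. Only cluster 6, with 18 and 10 cells, had all 8, with Il7r at 53.9 and 51.3 CPM. Eomes was detected in 6.36% of WT and 16.8% of Il7rKO NK-like cells. T cell-like cells were nearly missing from Il7rKO, with 2 of 700 cells (0.286%, 0.0346 to 1.03) against 1569 in WT (20.8%, 19.9 to 21.8), a ratio of 72.9 (20.2 to 603). ILC3/LTi-like cells, the innate lymphocytes that make IL-22 and help build lymphoid tissue, were 28.9% (27.9 to 30.0) and 19.3% (16.4 to 22.4), lower in Il7rKO at 0.667 times the WT share (0.556 to 0.794). Migratory DC-like cells were 5.10% and 6.57% (4.85 to 8.67), a ratio of 1.29 with an interval from 0.928 to 1.75, so a difference was not detectable with this clustering. That depends on the clustering. On the log2 scale the ratio was 0.37 (−0.11 to 0.81), but 1.39 with libraries clustered separately and 1.0995 with WT drawn down. Under the other alternatives that gave a value it stayed inside that interval.

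Counted per Aire APC-like cell, WT had 5.67 ILC3/LTi-like, 2.62 NK-like, 4.09 T cell-like and 1.00 migratory DC-like cells. In Il7rKO these numbers were 0.549, 0.919, 0.00813 and 0.187. The last of these depends on the clustering: Il7rKO had 46 migratory DC-like and 246 Aire APC-like cells here, but 95 and 163 with libraries clustered separately (390 and 387 in WT) and 90 and 201 with WT drawn down (42 and 24 in WT). Each was lower in Il7rKO, so a share that was higher there does not by itself show more cells of that class. Small classes were cDC1-like, with 37 and 3 cells, and macrophage-like, with 65 and 4.

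Within the ILC3/LTi-like class the clusters differed in weight. Cluster 16, led by Upp1, Igfbp7, Il22, Fam184b, Tnfsf8 and Cd4, held 833 WT cells (38.2% of the class) and 2 Il7rKO cells (1.48%). Clusters 8, 11 and 12 held 138, 724 and 483 WT cells and 30, 49 and 54 Il7rKO cells. Cluster 16 is nearly all of 1 library and may be a state of that library as well as a cell type. The migratory DC-like class was also split: cluster 14 held 97 WT and 38 Il7rKO cells, and cluster 15, led by Fmnl2, Fscn1 and Il12b, held 287 and 8.

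Unnamed clusters made up 25.3% of WT cells and 5.43% of Il7rKO cells. Those with too few markers were 21.7% and 3.71%, those led by cell cycle genes 3.37% and 1.71%, and the 1 with markers of 2 types 0.239% and 0. Cluster 19 held 17 of the 26 Il7rKO cells with too few markers, at a median depth 0.131 times that of the library. It was matched to the macrophage list, of which 2 markers were found, but carried 10 migratory dendritic cell markers. Its Il7rKO cells had Aire at 259 CPM. All shares are of cells that passed the tdTmt and MHC class II gates, and the libraries differ in number of cells and in median depth, each of which can set a share. When each library was clustered on its own, the log2 ratio of shares was 2.18 for Aire APC-like cells, against 2.78, and 1.39 for migratory DC-like cells, against 0.37.

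**Figure D2:**
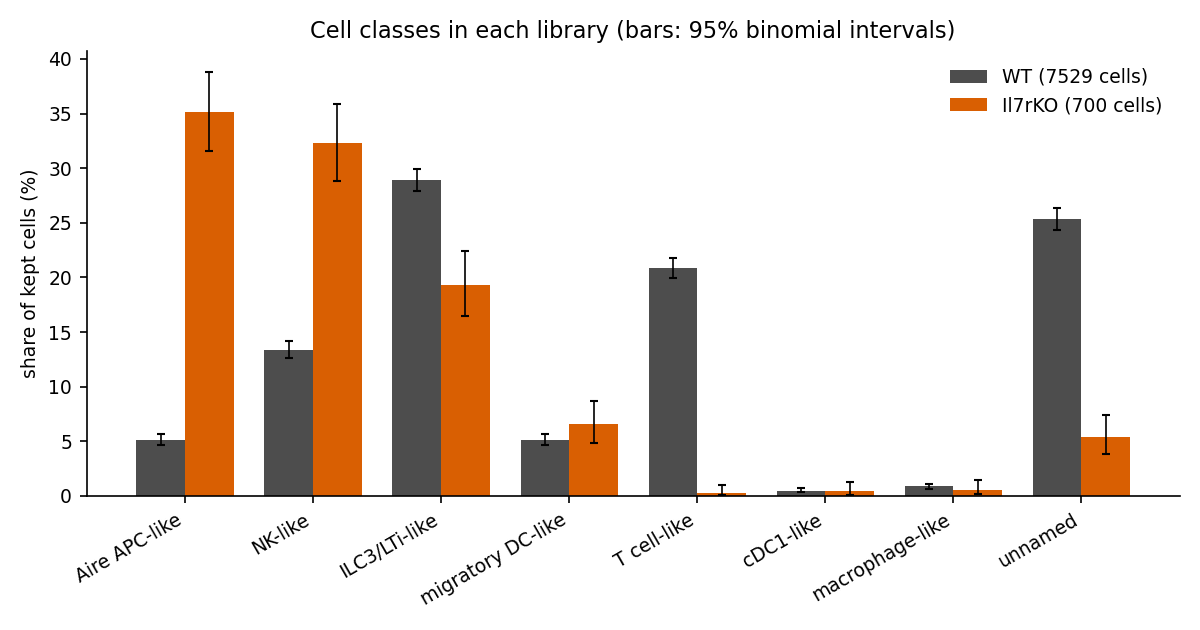
Share of kept cells in percent for each named class and for unnamed clusters in WT and Il7rKO, with exact binomial 95% intervals. Aire APC-like cells were 5.10% of WT and 35.1% of Il7rKO, and T cell-like cells 20.8% and 0.286%.

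The third comparison is of gene levels within Aire APC-like cells, 384 in WT and 246 in Il7rKO, from 13063982 and 13187925 UMIs. Some genes that mark this class had close levels in both libraries: Aire was 216 CPM in WT and 222 in Il7rKO, Prdm16 1064 and 1083, and Col17a1 364 and 350. Of the others, Trp63 was 248 and 346 CPM, Kif21a 146 and 187, and Ncam1 119 and 88.8. Itgb8, an integrin chain that activates TGF-beta, was 390 and 452 CPM. Outside the class, Aire was 1.40 CPM in WT and 4.70 in Il7rKO. Transcription factor Klf2, which keeps lymphocytes quiescent, was 1.99-fold lower in Il7rKO (1.88 to 2.11; 258 against 129 CPM). Class II presentation genes as a list, with a median log2 ratio of −0.08, were inside the random range.

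Beyond Klf2, some members of the IL-7 receptor signalling list were lower, though the list as a whole was not outside the random range (median −0.07, percentile 23.25, 10 of 18 members lower, 4 of them by more than 1.5-fold). The survival factor Bcl2 was 55.3 CPM in WT and 25.9 in Il7rKO (log2 ratio −0.96), and the feedback inhibitors Cish and Socs1 were 8.19 against 2.65 (−0.79) and 59.7 against 34.8 (−0.70). Klf2, Cish and Socs1 were each higher in WT NK-like than in WT Aire APC-like cells, and WT had more lymphocytes per Aire APC-like cell. How much of the WT levels here is lymphocyte RNA was not tested. Survival and apoptosis genes were below the random range, with a median of −0.17 (percentile 1.29) and 11 of 14 members lower, Bcl2 and Bax (96.1 against 63.8 CPM) first among them.

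Dissociation stress genes, which cell handling induces, were lower in 18 of 18 members, with a median of −0.33 (percentile 0.0), led by Jund (444 against 256 CPM) and Ier2 (104 against 68.1). Genes of the mitochondrial genome were higher in 11 of 11, with a median of 0.35 (percentile 100), such as mt-Nd3 (125 against 250 CPM) and mt-Nd2 (607 against 962). Cell cycle genes had a median of 0.17 (percentile 99.96), with 12 of 20 higher, such as Cenpf (26.9 against 59.8 CPM) and Ccnb2 (8.34 against 17.2). That direction turned under 4 alternatives, to −0.87 when the libraries were clustered separately, where Cenpf was at −2.15 and Ccnb2 at −1.15. Follicular B cell genes had a median of 0.12 (percentile 97.745, 7 of 10 higher), which turned under 2 alternatives, while its member Klf2 was lower. Immunoglobulin constant genes had a median of −0.46 over 4 members (percentile 0.07), with Igkc at 74.7 against 38.4 CPM and Jchain at 3.75 against 0.607. Of the WT UMIs, 1 cell held 22.7% for Igkc and 51.0% for Jchain, and their ratios of −0.88 and −0.64 were −0.60 and −0.33 without the top cell of each library.

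Among single genes, the highest ratio was that of Slc15a2, a peptide transporter, at 0.612 CPM in WT and 161 in Il7rKO, 264-fold higher (134 to 611). Others among the highest were ENSMUSG00000121482 (6.28 against 79.1 CPM; log2 2.90), Hebp1 (34.3 against 187, 2.29), Cdk8 (329 against 1253, 1.91), Camk1d (1383 against 4914, 1.83), Slc1a3 (25.5 against 91.7, 1.66), Cxcl9 (32.9 against 97.7, 1.44), Il2 (51.4 against 146, 1.42) and Wnt5b (26.7 against 75.8, 1.35). For Cxcl9, 54.4% of the Il7rKO UMIs came from 1 cell, and the ratio was 0.72 without the top cell of each library. Il2 turned to −2.77 when the libraries were clustered separately. The levels of Cdk8 and Camk1d followed the summed level of Cmss1, Gphn and Lars2, a set chosen after its values were seen, from cell to cell in Il7rKO, with a Spearman rho of 0.84 and 0.68 in this class, above the central 95% of genes of like level. In WT cells of this class the rho was 0.53 and 0.71, also above that range.

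Lowest in Il7rKO was Klrb1b (100.0 against 27.1 CPM, −1.71), and other low ratios were those of Emb (180.3 against 63.2, −1.44), Klri1 (52.6 against 16.5, −1.42), Dhx40 (92.5 against 40.8, −1.09, with 31.7% of the WT UMIs in 1 cell and −0.66 without the top cells), Mgam2-ps (52.7 against 22.4, −1.07), Cnnm2 (61.9 against 27.1, −1.06), Ebf1 (64.3 against 29.3, −1.02), Ets1 (79.8 against 37.3, 2.14-fold lower) and Klf2 (−0.97). Klrb1b, Emb and Ets1 are lymphocyte genes that were at 1424, 3167 and 1336 CPM in WT NK-like cells, and WT had more NK-like, ILC3/LTi-like and T cell-like cells per Aire APC-like cell.

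**Figure D3:**
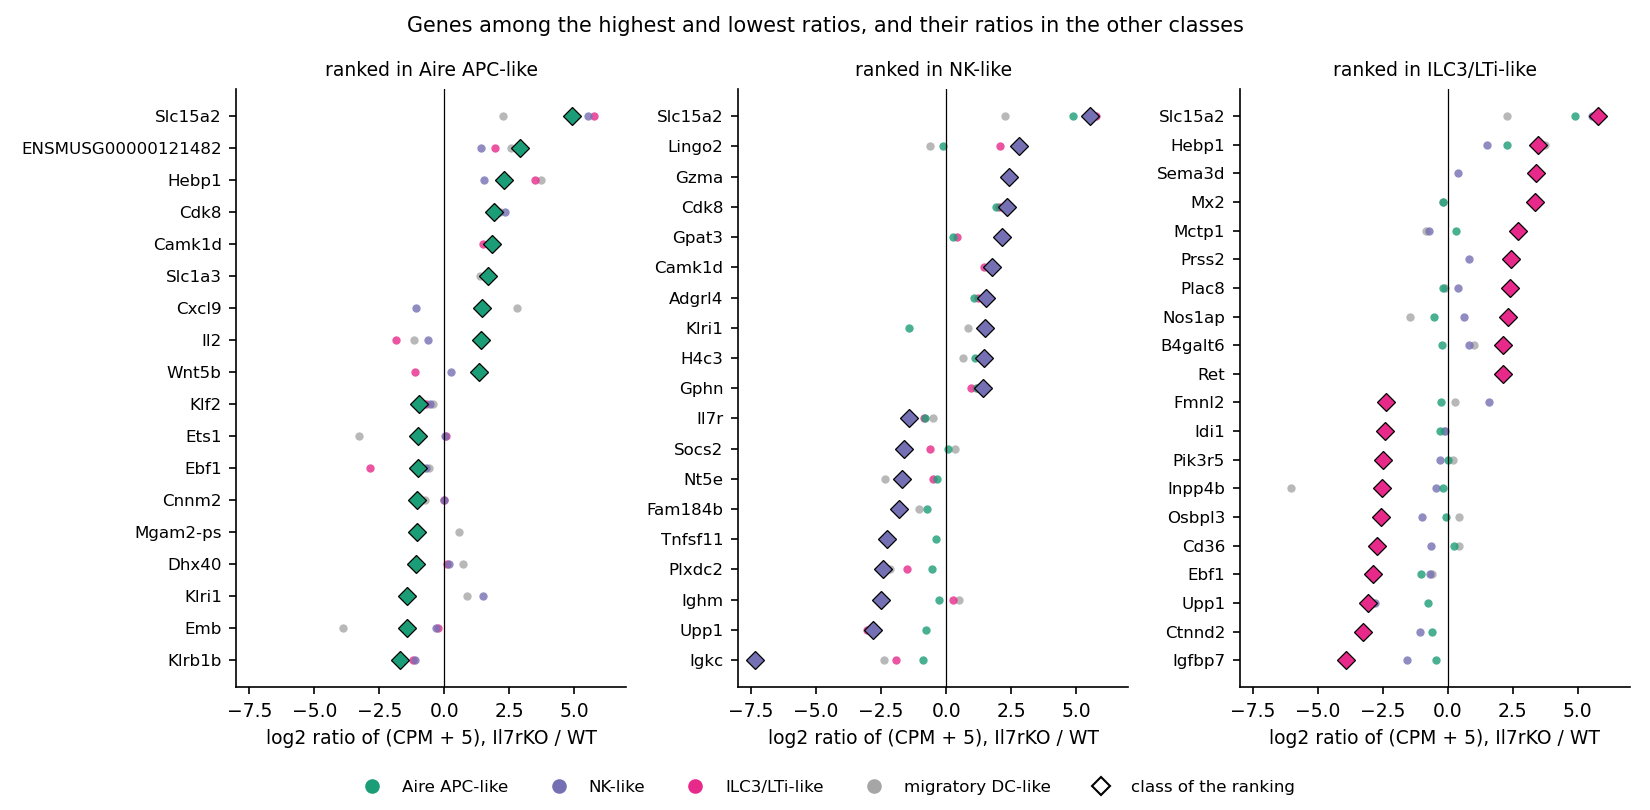
Log2 ratio of CPM plus 5, Il7rKO over WT, for genes among the highest and lowest ratios in 3 classes (diamonds) and for the same genes in the other classes (dots), 1 library per group. Slc15a2 had the highest ratio in Aire APC-like (4.89), NK-like (5.53) and ILC3/LTi-like cells (5.77).

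The fourth comparison is within NK-like cells, 1006 in WT and 226 in Il7rKO. Cluster 5, in which Il7r was high in WT (2050 CPM), was 72.7% of the class in WT and 82.3% in Il7rKO, so the class may not be only NK cells. Of the genes that mark NK cells, Ncr1 (520.3 against 529.7 CPM) and Nkg7 (439.9 against 442.7) had close levels, Klrb1c (488 against 303) and Klrd1 (244 against 186) were lower in Il7rKO, and Prf1 (88.0 against 146), Klre1 (116 against 175), Eomes (20.8 against 33.7) and Gzma were higher. Gzma, a granzyme of cytotoxic granules, was 84.0 CPM in WT and 471 in Il7rKO, 5.60-fold higher (5.24 to 5.99), in 4.08% and 9.29% of the cells. Cluster 6, led by Gzma, held 18 WT and 10 Il7rKO cells, and with WT clusters weighted to the Il7rKO mix the log2 ratio was 1.25, against 2.42. Tnfsf11, the cytokine RANKL, was 99.8 against 16.9 CPM, 5.90-fold lower (4.84 to 7.27), and Nt5e, the ectoenzyme CD73, 152 against 43.4.

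The IL-7 receptor signalling list had a median of −0.10 in NK-like cells (percentile 4.86, 10 of 18 lower). Socs2, a gene induced by STAT5, was 70.9 against 19.8 CPM (−1.61), Socs1 75.7 against 43.4 (−0.74), Cish 75.5 against 47.5 (−0.62) and Klf2 434 against 296 (−0.55). Cell cycle genes had a median of 0.19 (percentile 99.72, 9 of 14 higher), such as Top2a (14.4 against 40.8 CPM) and Mcm5 (10.9 against 22.3), which turned to −0.10 with cells thinned before clustering. Mitochondrial genome genes were higher in 9 of 11 (median 0.24, percentile 99.98), including mt-Nd3 (126 against 232 CPM) and mt-Nd2 (725 against 1031). Dissociation stress genes were lower in 14 of 18 (median −0.14, percentile 1.12), including Jund (1409 against 969 CPM) and Dusp1 (412 against 311).

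Co-stimulation and checkpoint genes were also below the random range in NK-like cells, with a median of −0.22 (percentile 0.26, 7 of 10 lower), from low levels of Cd80 (7.96 against 1.95 CPM) and Cd86 (3.95 against 1.46). B cell activation genes had −0.17 (percentile 0.68, 8 of 14 lower), with Egr3 at 29.0 against 11.2 CPM. Marginal zone B cell genes had −0.18 (percentile 1.61, 6 of 10 lower), with Cd36 at 3.48 against 0.488 and Myof at 3.81 against 0.813 CPM, which turned positive under 6 alternatives. Without the top cells the ratios of Cd36 and Myof were −0.27 and −0.22, against −0.63 and −0.60. The co-stimulation median turned to 0.32, Cd80 to 0.17 and Myof to 0.049 with WT drawn down, and Cd86 turned to 0.55 with cells thinned before clustering. Immunoglobulin constant genes had a median of −2.50 with 5 of 5 lower. This rests on single WT cells, as 1 cell held 97.7% of the Igkc UMIs (949.6 against 0.813 CPM) and 1 held 79.8% of those of Ighm (718 against 123). Without the top cell of each library the ratios were −2.30 and −0.26, and that of Jchain (37.2 against 0 CPM, at least 76.3-fold lower) was −0.30.

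The highest ratio in NK-like cells was again that of Slc15a2 (0.870 against 266 CPM), 306-fold higher (178 to 576). It was followed by Lingo2 (9.50 against 97.1, 2.82), Gzma, Cdk8 (330 against 1701, 2.35), Gpat3 (17.3 against 92.9, 2.14), Camk1d (1714 against 5854, 1.77), Adgrl4 (33.6 against 107, 1.53), Klri1 (31.8 against 99.4, 3.13-fold higher), H4c3 (21.7 against 67.7, 1.44) and Gphn (609 against 1625, 1.41). A single Il7rKO cell held 47.2% of the Lingo2 UMIs, and the Lingo2 ratio turned negative under 4 alternatives. The Spearman rho of Cdk8, Camk1d and Gphn with the other genes of the set named above was 0.77, 0.84 and 0.71 in Il7rKO, and 0.38, 0.46 and 0.23 in WT. Klri1 was lower in Il7rKO Aire APC-like cells and higher here. Other low ratios, beside those of Igkc and Ighm, were those of Upp1 (58.8 against 4.07, −2.81), Plxdc2 (252 against 42.9, −2.42), Tnfsf11 (−2.26), Fam184b (138 against 35.6, −1.81), Nt5e (−1.70), Socs2 and Il7r (−1.42).

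The fifth comparison is within ILC3/LTi-like cells, 2178 in WT and 135 in Il7rKO, and it sets a class of which cluster 16 is 38.2% in WT against one in which it is 1.48%. The IL-23 receptor gene Il23r was 1295 CPM in WT and 1143 in Il7rKO, Kit 448 and 460, and Il22 827 and 598. Tnfsf11 (RANKL), through which these cells act on stroma, was 654 against 125 CPM, 5.21-fold lower (4.67 to 5.83), and its log2 ratio of −2.34 was −2.22 with WT clusters weighted to the Il7rKO mix. Thy1 was 128 against 41.4 CPM. The feedback inhibitors Socs1 (111 against 40.7 CPM, −1.35) and Cish (141 against 52.8, −1.34) were lower, while Stat5b (147 against 263, 0.81) and Stat5a (46.9 against 82.5, 0.75), the transcription factors downstream of the receptor, were higher.

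Over the whole IL-7 receptor signalling list, 12 of 18 members were lower in ILC3/LTi-like cells (median −0.16, percentile 5.32). Cholesterol synthesis genes were lower in 9 of 9 (median −0.39, percentile 0.905), with Idi1 at 103 against 15.2 CPM and Sc5d at 14.8 against 5.70, and the median with weighted WT clusters was −0.39 as well. Lymphotoxin and lymphoid tissue genes were lower in 7 of 9 (median −0.44, percentile 0.18), Tnfsf11 and Tnfsf14 (36.7 against 17.5 CPM) most, but with weighting the median was −0.07. MHC class I genes were lower in 10 of 10 (−0.25, percentile 2.11, weighted −0.02), with H2-K1 at 1755 against 1164 and Psmb9 at 76.0 against 59.3 CPM. Oxidative phosphorylation (−0.32, percentile 0.15, weighted −0.20, 15 of 16 lower), glycolysis (−0.28, percentile 1.21, weighted −0.19, 12 of 13 lower) and ribosomal protein genes (−0.21, percentile 0.99, weighted −0.10, 15 of 18 lower) were also below the random range. Examples are Cox6c (230 against 141 CPM), Ndufa4 (137 against 89.7), Pgk1 (47.6 against 26.6), Pfkp (151 against 98.8), Rps14 (1526 against 1003) and Rpl18 (770 against 581), and the ribosomal median was 0.0018 with libraries clustered separately. Weighting also lowered some lists that were inside the random range, among them class II presentation (−0.17, weighted −0.49), B cell activation (−0.18, weighted −0.47), B-1 cell (0.085, weighted −0.22), tolerance-associated (−0.18, weighted −0.30) and dissociation stress genes (0.0084, weighted −0.42).

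Slc15a2 again led the ILC3/LTi-like ranking (0.572 against 299 CPM, 522-fold higher, 320 to 918). Next were Hebp1 (3.54 against 89.7, 3.47), Sema3d (7.72 against 128, 3.38), Mx2 (2.29 against 69.2, 3.35), Mctp1 (9.69 against 90.4, 2.70), Prss2 (8.33 against 67.3, 2.44), Plac8 (9.11 against 68.8, 2.39), Nos1ap (17.4 against 105, 2.30), B4galt6 (13.5 against 76.8, 2.14) and Ret (7.72 against 50.2, 2.12). Of the Il7rKO UMIs of Mx2 and Ret, 49.5% and 43.2% came from 1 cell each, and without the top cells their ratios were 2.67 and 1.46. The lowest were Igfbp7 (152 against 5.32, −3.92), Ctnnd2 (75.8 against 3.42, −3.26), Upp1 (160.3 against 14.8, −3.06), Ebf1 (70.1 against 5.32, −2.86), Cd36 (53.4 against 3.80, −2.73), Osbpl3 (165 against 23.9, −2.56), Inpp4b (159 against 23.2, −2.54), Pik3r5 (70.8 against 8.36, −2.50), Idi1 (−2.41) and Fmnl2 (58.8 against 7.22, −2.38). Igfbp7 and Upp1, which lead cluster 16, had ratios of −3.01 and −1.97 with weighted WT clusters, and Cd36 had −1.44.

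**Figure D4:**
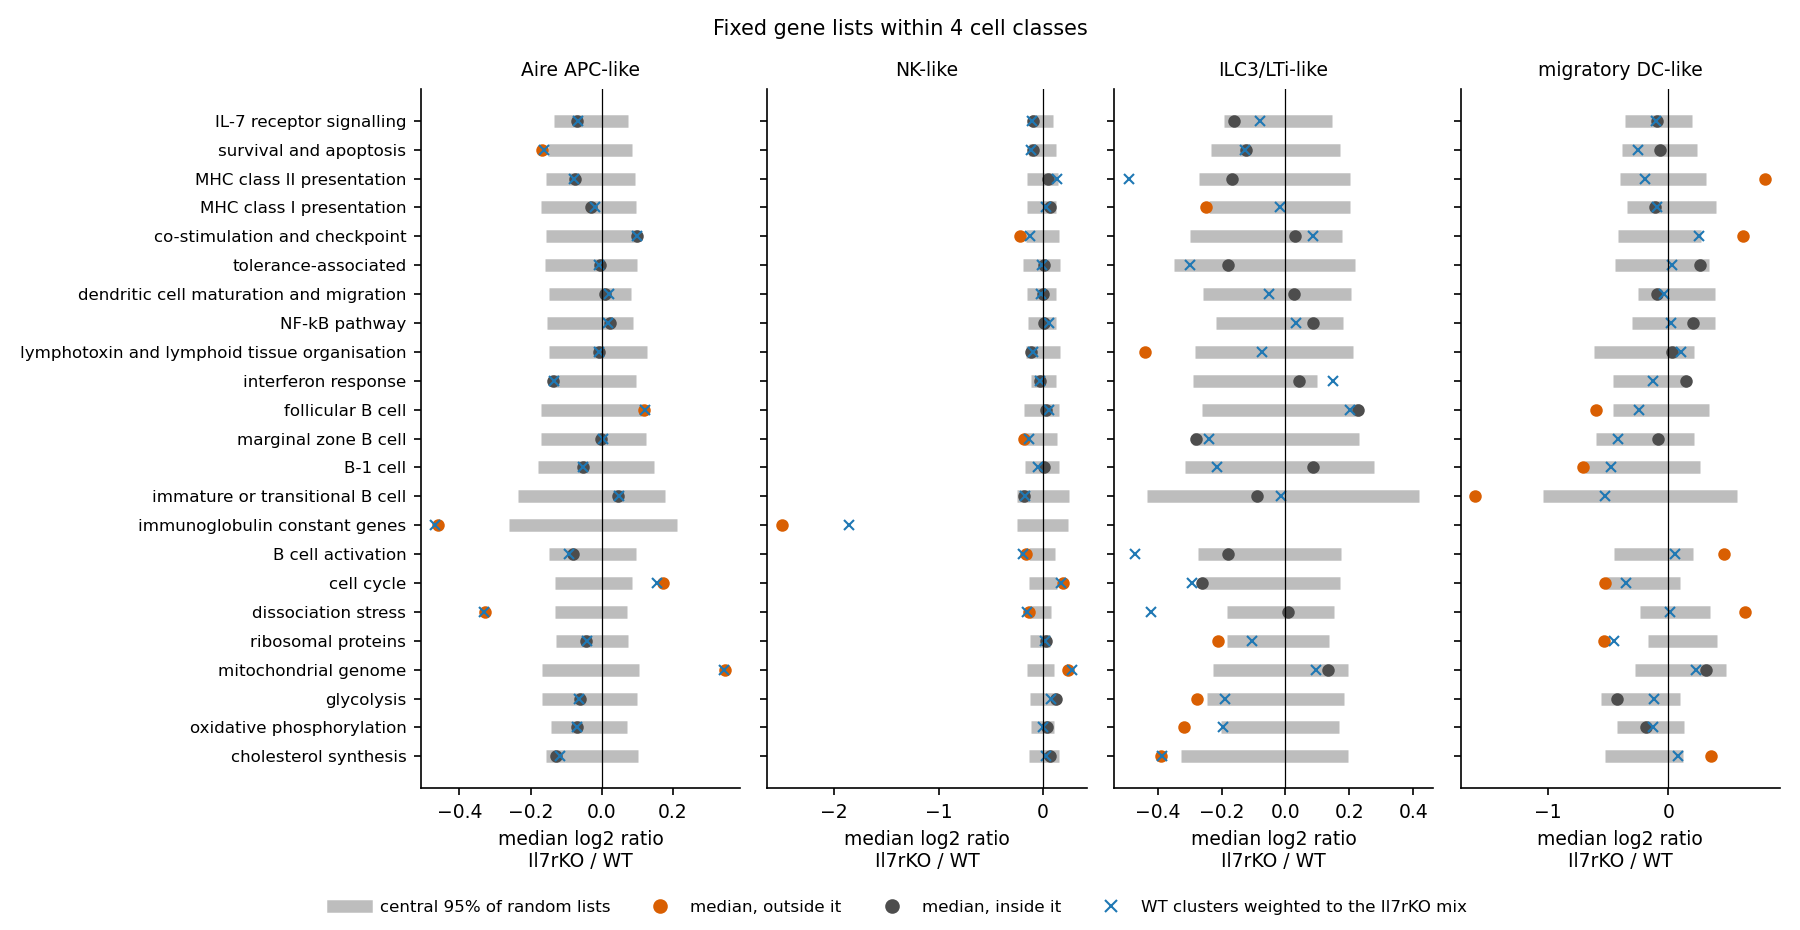
Median log2 ratio, Il7rKO over WT, of each fixed gene list in each compared class, beside the central 95% of 10000 matched random lists (bars), with crosses for WT clusters weighted to the Il7rKO mix. In Aire APC-like cells dissociation stress genes had the lowest percentile (0.0) and mitochondrial genome genes the highest (100).

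The sixth comparison is within migratory DC-like cells, 384 in WT and 46 in Il7rKO, where cluster 15 was 74.7% of the WT class and 17.4% of the Il7rKO class. Hebp1 (14.8 against 258 CPM, 3.73), Klra17 (1.63 against 80.1, 3.68) and Ryr3 (19.6 against 203, 3.07) had the highest ratios, and 55.9% of the Ryr3 UMIs came from 1 Il7rKO cell (2.31 without the top cells). The T cell genes Lef1 (429 against 0.404 CPM) and Inpp4b (481 against 2.43, −6.03) were among the lowest. The ratio of Lef1 rests on 1 UMI in Il7rKO, as a 1059.5-fold lower level (190.1 to 41856). In WT cluster 15, 192 of 287 cells (66.9%, 61.1 to 72.3) had at least 5 UMIs of T cell marker genes, against 5 of 97 in WT cluster 14 and 1 of 38 in Il7rKO cluster 14. The median log2 ratio of all genes in this class was −0.22, and median-ratio scaling moved the log2 ratio of Il7r from −0.49 to −0.35.

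Class II presentation genes were higher in 11 of 12 members in the Il7rKO migratory DC-like class (median 0.81, percentile 100), with Ciita, their master regulator, at 45.2 against 155 CPM and H2-Ab1 at 604 against 1577. With WT clusters weighted to the Il7rKO mix that median turned to −0.19 and H2-Ab1 to −0.11. Weighting also moved the medians of co-stimulation and checkpoint genes (0.62, percentile 99.98, weighted 0.26, and −0.028 with libraries clustered separately), B cell activation genes (0.46, percentile 99.93, weighted 0.06), dissociation stress genes (0.64, percentile 100, weighted 0.01) and cholesterol synthesis genes (0.35, percentile 99.88, weighted 0.08). Their named members were Havcr2 (14.5 against 45.3 CPM), Tnfsf4 (39.1 against 73.2, with 69.1% of Il7rKO UMIs in 1 cell, −0.31 without the top cells and −1.01 with WT drawn down), Nr4a3 (1091 against 2475), Cd69 (63.5 against 25.5), Hsph1 (516 against 1084), Hspa1a (662 against 1327) and Hmgcs1 (110 against 190, log2 0.77 and 0.03 without the top cells).

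Lists below the random range in migratory DC-like cells were follicular B cell (−0.60, percentile 0.49, weighted −0.24), B-1 cell (−0.71, percentile 2.28, weighted −0.48), immature or transitional B cell (−1.61, percentile 0.535, weighted −0.53), cell cycle (−0.53, percentile 2.05, weighted −0.35) and ribosomal protein genes (−0.54, percentile 0.0, weighted −0.45, 18 of 18 lower). Their largest members are genes that T cells also express: Satb1 (603 against 19.0 CPM), Bach2 (364 against 9.71), Cd5 (53.3 against 0.404, 1 UMI), Ctla4 (60.1 against 2.43), Myb (74.9 against 15.8) and Il2ra (66.9 against 18.6). Stmn1 was 17.1 against 4.45 CPM, Cenpa 26.1 against 10.5, Rpl5 1118 against 564 and Rplp1 2719 against 1504. The B-1 and immature B cell medians and Il2ra turned positive with libraries clustered separately or WT drawn down, as did Myb with WT drawn down (0.16) and Cenpa with libraries clustered separately (0.25). Of the IL-7 receptor signalling list (median −0.10, percentile 47.4), Bcl2 was 119 against 9.30 CPM (−3.12; weighted −1.54), Cish 8.76 against 1.21, Pim2 13.2 against 4.04 and Jak1 513 against 259. How much of these WT levels is T cell RNA was not tested. In WT cluster 15, 66.9% of cells had at least 5 UMIs of T cell marker genes.

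Of the 23 fixed lists, 23 could be measured in Aire APC-like and NK-like cells and 22 in each of the other classes, and 6, 7, 6 and 10 were outside the random range, in the order of the comparisons. Across genes, log2 ratios in Aire APC-like cells followed those in NK-like cells with a Spearman rho of 0.33 and those in ILC3/LTi-like cells with 0.29, and the rho between the last 2 classes was 0.31. Genes are not independent replicates, and these values describe 1 pair of libraries.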

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

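The tests on free RNA gene by gene, on DNA next to Il7r, on 1 RNA source and on the sort gates and Il7r level across clusters were chosen only after the result was seen. The other tests were set before their own values were computed, but after the patterns they address had been seen.

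Some gene lists were outside the random range in opposite directions in 2 classes, and none of these differences was tested. The median log2 ratio of migratory DC-like cells exceeded that of NK-like cells by 0.84 for co-stimulation and checkpoint genes, 0.62 for B cell activation genes and 0.77 for dissociation stress genes. It exceeded that of Aire APC-like cells by 0.96 for dissociation stress genes and that of ILC3/LTi-like cells by 0.74 for cholesterol synthesis genes. Follicular B cell genes were 0.72 higher in Aire APC-like than in migratory DC-like cells. Cell cycle genes were 0.70 higher in Aire APC-like cells and 0.72 higher in NK-like cells than in migratory DC-like cells. Each pair includes the migratory DC-like class, whose clusters 14 and 15 have different weights in the libraries, and the cholesterol pair also the ILC3/LTi-like class, of which cluster 16 is 38.2% in WT and 1.48% in Il7rKO. With WT clusters weighted to the Il7rKO mix, the migratory DC-like medians were 0.26 for co-stimulation and checkpoint, 0.06 for B cell activation, 0.01 for dissociation stress, 0.08 for cholesterol synthesis, −0.24 for follicular B cell and −0.35 for cell cycle genes. The co-stimulation and checkpoint median was −0.028 in migratory DC-like cells with libraries clustered separately and 0.32 in NK-like cells with WT drawn down, and cell cycle and follicular B cell genes in Aire APC-like cells and cell cycle genes in NK-like cells also turned under some alternatives.

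T cell genes were far lower in Il7rKO than in WT migratory DC-like cells. Free T cell RNA in the WT suspension is argued against, since WT migratory DC-like cells had 28.2 T cell marker UMIs per cell against 2.85 in WT Aire APC-like cells, a ratio of 9.90 (9.30 to 10.5). T cell RNA captured together with WT dendritic cells, as doublets or attached cells, is a candidate explanation: the WT excess over Il7rKO was 20.2% to 28.8% (quartiles over 10 markers) of the T cell-like level, a ratio of 1.43 between quartiles, and Il7rKO had only 2 T cell-like cells to be captured. Lower T cell gene levels in the same dendritic cell cluster without Il7r stay open, as the summed markers in cluster 14 had a log2 ratio of −2.68 (−3.41 to −2.03; 65.8 against 10.2 CPM), but WT cluster 14 had only 1.98 such UMIs per cell, and how much of these is free RNA was not measured. The MHC class II gate would remove T cells without that protein, yet 1569 WT cells were T cell-like, and of the 10 markers (Cd3e, at 380 CPM in WT T cell-like cells, Cd3d, Cd3g, Trac, Trbc2, at 816 CPM, Lck, Cd28, Cd5, Cd8a and Lat) Cd5 and Cd8a were also seen at 35.3 and 12.6 CPM in WT Aire APC-like cells.

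Of 9145 genes measured in Aire APC-like, NK-like and ILC3/LTi-like cells, 8 were higher in Il7rKO by a log2 ratio over 1 in each class (Slc15a2, Hebp1, ENSMUSG00000121482, Adgrl4, Camk1d, Cdk8, H4c3 and Ccnb1ip1) and 3 were lower (Tnfsf8, Klrb1b and Lyz2), a set chosen after its values were seen. Free RNA was not tested for the 3 lower genes and stays open for them. Lyz2 was at 13238 CPM in WT macrophage-like cells. Outside that class it was at 30.2 CPM in WT and 3.03 in Il7rKO. Free RNA that differs between the libraries is argued against for Hebp1, ENSMUSG00000121482 and Adgrl4. By the earlier test alone the result was undecided. UMIs per Il7rKO cell of the 8 genes had a median ratio of 1.51 between Aire APC-like and NK-like cells (quartiles 1.18 and 2.71, bound 1.3). All of these 8 except H4c3 and Ccnb1ip1 differed between classes by more than 1.3 times what depth allows. Hebp1 had 10.0 UMIs per Aire APC-like against 0.296 per NK-like cell, a ratio of 33.9 where depth gives 1.97. For Slc15a2, Camk1d and Cdk8 this rests on the 46 Il7rKO migratory DC-like cells. The ratios of Aire APC-like to these cells were 2.97, 0.698 and 0.737, where depth gives 0.997. Their ratios to NK-like cells, 1.20, 1.65 and 1.45, were within what depth gives. Free RNA stays open for Camk1d and Cdk8, and for Slc15a2 only this small class argues against it. DNA next to Il7r carried from the strain in which the gene was changed is argued against, since 0% of 10 genes with a known place lie on chromosome 15 within 20 Mb of Il7r. The third explanation is 1 RNA source, counted also in Cmss1, Gphn and Lars2, for the genes higher in Il7rKO. In at least 2 of the 3 main Il7rKO classes, 4 of the 8 genes followed the summed level of these 3 from cell to cell less than a source gene thinned to their UMIs over WT would, a result between both bounds, so for the set it cannot be told apart from other explanations. The 4 were Slc15a2, in 3 classes (in Aire APC-like cells a rho of −0.10, where 0.39 was the lower end for a thinned source gene), and Hebp1, ENSMUSG00000121482 and Adgrl4, in 2 each. H4c3 was below in 1 class, and Camk1d, Cdk8 and Ccnb1ip1 in 0. What sets Slc15a2 and Hebp1 apart stays open, and a difference between the mice or preparations was not tested, since each group has 1 library.

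Several clusters were nearly missing from Il7rKO, such as 16 (ILC3/LTi-like), 10 (unnamed) and the T cell-like clusters. For a stricter tdTomato gate in the Il7rKO sort, the Spearman rho across 24 clusters between the WT tdTomato level and the ratio of shares was −0.13 (−0.22 to −0.06 without each cluster in turn). At the mRNA level this argues against such a gate for these clusters. It cannot exclude one, because the gate acts on protein. The mRNA level was also low in clusters of few UMIs, such as 3 and 11, with medians of 0.377 and 0.388 times that of their library. Clusters 16 and 10 had 198 and 153 CPM of tdTomato in WT, while clusters low in tdTomato went both ways: 11 and 14, at 32.0 and 43.2 CPM, had log2 ratios of shares of −0.44 and 2.09, and 3 and 15, at 36.6 and 20.2 CPM, had −6.04 and −1.65. Whether such a gate acted on cells low in tdTomato also stays open, as the tdTomato level was higher in Il7rKO in migratory DC-like cells (74.4 against 24.9 CPM, and 83.8 against 43.2 in cluster 14 alone). A stricter MHC II gate in the Il7rKO sort is a candidate explanation for part of it, with a rho of 0.60 (0.56 to 0.66) for the WT level of MHC class II genes, though mRNA is not surface protein and cluster 5, at 458 CPM of these genes, had a log2 ratio of shares of 1.46 against −4.95 for cluster 16, at 2208 CPM. The rho cannot tell such a gate from a loss of lymphocytes, since the level follows cell type. T cell-like clusters had 111 to 178 CPM of these genes in WT, and Aire APC-like clusters 11795 and 18245. For cells with a higher Il7r level lost more often without Il7r, the rho of −0.27 (−0.36 to −0.18) leaves the explanation open, because it lies between both bounds set for it. The dependence of T cells and innate lymphocytes on interleukin-7 is the biological difference that the design names, and it could not be tested apart from the library, since each group has 1.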

How the results depend on the processing

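Removing the highest doublet scores, thinning before clustering, weighting WT clusters and leaving out the top cells were chosen only after the result was seen. No paired analysis was possible because each group has 1 library, no test was run between groups and the labels share no replicate numbers. The number of cells limits what can be seen in Il7rKO, with 46 migratory DC-like and 2 T cell-like cells and 17.4% of the former in cluster 15, while its median depth of 28974.5 UMIs per cell was above the 14892 of WT. The Il7r level was lower in Il7rKO, and the shares of the 5 classes compared kept their direction, under each alternative run that gave a value. On the log2 scale Il7r ranged from −1.88 to −1.62 over all cells, from −1.52 to −0.80 in Aire APC-like, from −0.94 to −0.60 in ILC3/LTi-like, from −1.71 to −1.36 in NK-like and from −0.83 to −0.29 in migratory DC-like cells. Log2 ratios of shares ranged from 2.18 to 3.07 for Aire APC-like, from 1.13 to 1.44 for NK-like, from −0.84 to −0.43 for ILC3/LTi-like, from −6.24 to −6.11 for T cell-like and from 0.19 to 1.39 for migratory DC-like cells. Of 1407 list medians under alternatives 1298 stayed, 88 moved and 21 reversed, and of 2049 values of named genes 1276 stayed, 756 moved and 17 reversed. A list median stayed if it lay in a band around the reported median, set by the width of the random range. A gene stayed if it lay in the counting interval of its ratio, widened to hold the reported value. Reversals were counted only for lists outside the random range and genes whose ratio interval excludes 1. Other changes of sign are counted as stayed or moved. Shares of cells with a UMI moved in 20 of 20 cases, all by thinning, which lowers them by construction. In migratory DC-like cells the share with an Il7r UMI was 92.4% in WT and 91.3% in Il7rKO, and 48.9% and 51.1% after thinning to 2000 UMIs. No value came from separate clustering for the T cell-like share (no Il7rKO T cell-like cells) or from WT drawn down for genes of Aire APC-like cells (24 WT cells, under the minimum of 30). For the values that follow, the cause was not tested.

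With libraries clustered separately, the log2 ratio of Il7r was −1.52 in Aire APC-like, −0.94 in ILC3/LTi-like, −1.71 in NK-like and −0.83 in migratory DC-like cells, and that of shares was 2.18 for Aire APC-like and 1.39 for migratory DC-like cells. In Aire APC-like cells, 11 lists were outside the random range against 6, and cell cycle (−0.87), follicular B cell (−0.44), Ccnb2 (−1.15), Cenpf (−2.15) and Il2 (−2.77) reversed. In migratory DC-like cells, B-1 cell (0.16), immature or transitional B cell (1.51), co-stimulation and checkpoint (−0.028), Cenpa (0.25) and Il2ra (1.97) reversed, as did ribosomal proteins in ILC3/LTi-like (0.0018) and Lingo2 in NK-like cells (−0.41).

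With WT drawn down, Il7r was −1.88 over all cells, −0.79 in ILC3/LTi-like and −1.68 in NK-like cells, and the ratio of shares was 3.07 for Aire APC-like and 1.0995 for migratory DC-like cells. In NK-like cells, 4 lists were outside against 7, and co-stimulation and checkpoint (0.32), marginal zone B cell (0.20), Cd80 (0.17) and Myof (0.049) reversed. In migratory DC-like cells, B-1 cell (0.20), immature or transitional B cell (1.01), Il2ra (1.01), Myb (0.16) and Tnfsf4 (−1.01) reversed.

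With cells thinned before clustering, Il7r was −1.62 over all cells, −1.19 in Aire APC-like, −0.61 in ILC3/LTi-like and −1.59 in NK-like cells. The lists outside were 4 in NK-like, 2 in ILC3/LTi-like and 5 in migratory DC-like cells, against 7, 6 and 10. Cell cycle (−0.071) and follicular B cell (−0.028) reversed in Aire APC-like cells, and cell cycle (−0.10), marginal zone B cell (0.40), Cd86 (0.55) and Lingo2 (−0.45) in NK-like cells.

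With the highest doublet scores removed, Il7r was −0.94 in Aire APC-like, −0.89 in ILC3/LTi-like and −0.29 in migratory DC-like cells, and cell cycle in Aire APC-like (−0.15) and marginal zone B cell in NK-like cells (0.049) reversed. With WT clusters weighted to the Il7rKO mix, Il7r was −1.36 in NK-like and −0.36 in migratory DC-like cells. There 5 lists were outside in migratory DC-like cells, and MHC class II presentation (−0.19) and H2-Ab1 (−0.11) reversed. Without the top cell of each library, Tnfsf4 in migratory DC-like cells was −0.31.

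The stricter barcode filter gave Il7r of −0.77 in ILC3/LTi-like and −1.49 in NK-like cells, 4 lists outside in NK-like cells, Lingo2 at −0.55 and marginal zone B cell at 0.0073 there. No filter gave marginal zone B cell in NK-like cells at 0.040 and cell cycle in Aire APC-like cells at −0.0023. Resolution 0.5 gave Il7r of −0.72 in ILC3/LTi-like and −1.54 in NK-like cells and marginal zone B cell of 0.020 in the latter. Resolution 2 gave Il7r of −1.55 and Lingo2 of −0.53 in NK-like cells, and doublet calls kept gave Il7r of −1.48 there. The mean over cells gave Il7r of −1.09 in Aire APC-like and −0.60 in ILC3/LTi-like cells. Median-ratio scaling gave Il7r of −0.35 in migratory DC-like cells, and CPM without immunoglobulin, mitochondrial and ribosomal genes −1.86 over all cells. With genes of 1 UMI in either library, 10 lists were outside in ILC3/LTi-like cells against 6.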

Other observations

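Some unnamed clusters had smaller shares in Il7rKO. Cluster 10, led by Ccr10, Il13, Itgae, Il17rb and Areg, several of which type 2 innate lymphocytes express, held 779 WT cells and 0 Il7rKO cells. Cluster 17, led by Il1rl1, the IL-33 receptor, with Il4, Il13 and Pparg, held 136 and 3 cells, and cluster 3 held 354 and 0. Cluster 23, led by cell cycle genes, held 105 and 2 cells. Cluster 21, also led by such genes, held 149 and 10, which is 1.98% of WT and 1.43% of Il7rKO cells. Clusters 10, 17 and 3 have no name here because they had too few markers of any list, and no list fixed for this work covers type 2 innate lymphocytes. Clusters 21 and 23 were left unnamed because cell cycle genes lead them.

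The tdTomato transcript was close in both libraries over all kept cells, at 120 CPM in WT and 112 in Il7rKO. It was highest in ILC3/LTi-like cells (171 and 184 CPM) and NK-like cells (159 and 166), lower in Aire APC-like cells (73.6 and 80.3), and lower again in WT migratory DC-like cells, where it was 24.9 CPM against 74.4 in Il7rKO. The cDC1-like cells had 6.39 CPM in WT (37 cells) and 20.5 in Il7rKO (3 cells, 6.65 to 47.8), and macrophage-like cells 8.91 in WT (65 cells) and 151 in Il7rKO (4 cells, 104 to 211, in which the macrophage gene Lyz2 was at 100 CPM against 13238 in WT). No gfp UMI was counted in either library. Xist was at 1025 and 855 CPM, and of the Y-linked genes the most counted was Ddx3y, with 20 UMIs in WT and 0 in Il7rKO.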
